A study of Homo sapiens with 9 samples.

How the data were processed

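RNA from formalin-fixed, paraffin-embedded tissue of 9 human tumours, all given as nodular fasciitis carrying a USP6 fusion, was profiled on Illumina HumanHT-12 v4 BeadChips with the WG-DASL assay, per the labels' protocols. WG-DASL copies short targeted stretches of degraded RNA before hybridisation, and each gene is read by 1 or a few probes. The labels give a single group and no control tissue. Apart from the numbered titles, nothing says that the arrays came from separate donors, so p-values measure only the spread between these samples, which may in part be technical.

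The deposited probe table holds, per the file headers, a bead-averaged intensity per probe and array and a detection p-value for each. GenomeStudio is named without a version in the submitters' processing notes. These intensity values were linear, had a different median on each array and never fell below 0. The deposited value table holds a second set of intensity values that the authors had normalized: every array had nearly the same quantiles, and the rank correlation with the unnormalized values was 1 on each array. Scale was linear and genes were not centred. The target of that normalization stays unknown, since its quartiles (349, 1747 and 6846) differed from those of the mean of these 9 arrays (195, 1599 and 7270). Array medians in the deposited value table were 1747 on all arrays.

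The unnormalized intensities were background-corrected and quantile-normalized with neqc of limma 3.58.1 in R 4.3.3, which estimates the background from the detection p-values, with an offset of 16, and put on the log2 scale. The normalized values ran from 5.59 to 16.09 with a median of 12.32, so differences of genes near either end are compressed. Probe levels are not comparable between genes, so a gene called high has a high place on this scale only. The tables held 29377 probes. A single gene symbol was given for 27988 of them in the platform annotation, none for 1389 (unnamed here) and several for 0. Symbols were updated through Entrez identifiers for 27819 probes with a RefSeq gene table of assembly GRCh38.p14, used for names alone. XIST, TSIX, Y-linked genes, HLA genes and genes with common whole-gene deletions were left out, which removed 140 probes. Of the 19319 named genes, 5697 had several probes, and the probe with the highest mean was used. A gene was kept for tests if its probe was detected at p below 0.01 on at least 5 of the 9 arrays, which left 14234 genes.

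The design fixed at the start assumed 9 separate tumours. Arrays 1, 6 and 7 turned out to be far more alike than any other pair of arrays. They were averaged and counted as 1 sample, called the averaged sample here, which left 7 samples. The SD over the 3 arrays is given for some genes as a description; whether it measures technical error alone was not settled. All 9 arrays as separate tumours were run as an alternative chosen after the data were seen. The filter of 5 arrays counts the 3 arrays separately.

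Gene lists, tests, alternatives and the rule for named genes were chosen before the data were examined. Named genes were USP6, the 25 kept genes with the largest SD between samples, the first 3 members of each list with a probe and its 2 kept members with the largest SD, the USP6 list in full, and the 3 genes with the smallest p in each direction on USP6. Other genes, where named, were chosen after their values were seen and are said to be so. A list score is the mean of its members' log2 values after each gene was centred over the samples, for lists with at least 5 kept genes. The spread of a list is the median SD of its members, placed as a percentile among 10000 random lists of the same size matched on mean level in 20 bins. Lists at or above percentile 95 were counted. This percentile describes these samples and is no test.

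Correlations over 7 samples were tested with exact 2-sided permutation over all orders of the samples, for which the smallest p is 0.000198, and adjusted by Benjamini-Hochberg. Genes were fitted on the USP6 level with limma, with an adjusted p threshold of 0.05. The BeadChip positions in the labels give a technical batch: 5 arrays lay on the first BeadChip and 4 on 3 others, and both sets were compared with limma and with exact permutation of list scores over 126 regroupings. The fits were checked on simulated data with 200 genes changed by a known size. For the USP6 fit over 14233 genes, 0, 123 and 171 of them were recovered at slopes of 1, 2 and 4 log2 units per unit of USP6, with 0, 6 and 13 false calls. For the BeadChip fit over 14234 genes, 0, 112 and 173 were recovered at differences of 1, 2 and 4, with 0, 9 and 13 false calls.

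Alternatives were the deposited normalized values, no background correction, an offset of 50, other detection filters, the mean of a gene's probes, leaving out each array, BeadChip set as a block (the averaged sample entered by its share of arrays in each set), the number of detected probes as a covariate, array weights, z-scored genes and Spearman's rho. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. Second marker lists for keratinocytes, skeletal muscle and adipocytes were written before their values were seen and are used in the closing observations.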

Results

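Nodular fasciitis is a self-limited growth of fibroblasts and myofibroblasts in which the ubiquitin protease gene USP6 is commonly activated by fusion to the promoter of another gene. Transcript levels were measured on 9 arrays of fixed tumour tissue, all in 1 group. Median unnormalized intensity per array ran from 919 to 2707, and between 18864 and 21638 of the 29377 probes (64.2% to 73.7%) were detected at p below 0.01. The number of arrays limits the precision of every value.

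Arrays 1, 6 and 7 carried nearly the same profile. Rank correlations of unnormalized intensities over all probes were 0.988 to 0.990 among them, against 0.820 to 0.940 for all other pairs. Over kept genes the SD of their normalized log2 differences was 0.33 to 0.39, against 1.0 to 1.79. The SD over these 3 arrays was 0.20 for the contractile gene CNN1 and larger for some genes that were dim there, at 0.69 for KRT14, 0.73 for ADIPOQ and 0.85 for SFN. Some genes far from the floor there had large values too: NR4A1 (0.64 at a level of 12.26), RUNX2 (0.52 at 12.90) and RPL8 (0.49 at 12.96). For RUNX2 and RPL8 the SD over the 7 samples was little larger, at 0.67 and 0.56. They lay on 3 BeadChips. Since the gap to all other pairs was this wide, the 3 arrays were averaged and counted as 1 sample. Bead counts were not used here, so whether they differed by less than the bead-level noise was not tested. The median SD of a gene was 0.16 over the 3 arrays and 0.65 over the 7 samples.

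**Figure D1:**
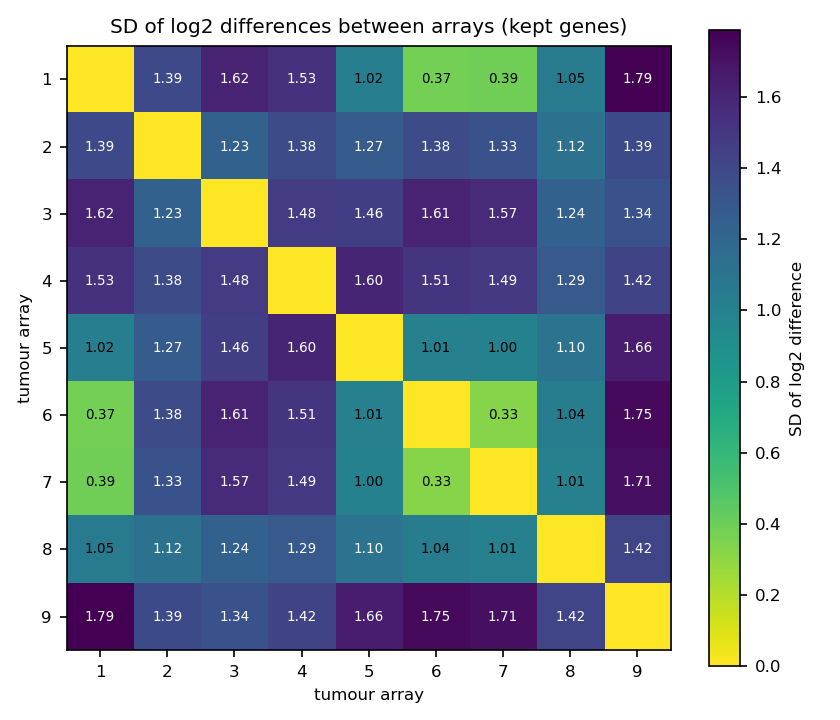
Each cell gives the SD of log2 differences over kept genes between the arrays named on the axes. Pairs among arrays 1, 6 and 7 stand at 0.33 to 0.39 and all other pairs at 1.0 to 1.79.

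USP6, the gene rearranged in this tumour, was detected on every array. Its log2 level was 13.48 ± 0.73 (SD, n = 7), lowest in tumour 4 at 12.11 and highest in tumour 3 at 14.32. The SD over arrays 1, 6 and 7 was 0.08. Without tumour 4 the SD was 0.45. All 13 members of the list of USP6 and genes reported as its fusion partners that had a named probe were detected on all 9 arrays. The non-muscle myosin gene MYH9, the commonest partner in nodular fasciitis, stood at 15.56 ± 0.11 (n = 7) and RRBP1 at 16.04 ± 0.02, near the top of the scale at 16.09. SEC31A (15.38 ± 0.16), CNBP (14.99 ± 0.36), CALU (14.91 ± 0.29), SERPINH1 (14.57 ± 0.37), CTNNB1 (13.86 ± 0.44), THRAP3 (13.53 ± 0.21), EIF5A (13.28 ± 0.48) and PPP6R3 (13.10 ± 0.34) also varied little (SD, n = 7). Larger spread was seen for CDH11, a mesenchymal cadherin, at 14.51 ± 1.12 and for OMD, a bone matrix proteoglycan, at 12.97 ± 1.39. The array reads USP6 with 1 probe, and signal from its close relatives USP32 and TBC1D3, for which there was no named probe here, was not separated. With no control tissue, these levels say nothing about an increase over normal tissue.

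The first question was which programmes were present in all tumours. Of 19319 named genes, 11733 (60.7%) were detected on all 9 arrays, 4859 on some and 2727 on none. Detection on every array covered all 24 fibroblast and matrix genes, all 17 interferon response genes, all 13 hypoxia and glycolysis genes, all 12 mitochondrial respiration genes and all 11 TGF-beta and BMP response genes with a probe. It also covered 13 of 14 contractile genes, 12 of 13 immediate early genes, 12 of 13 ribosomal protein genes, 11 of 12 macrophage genes, 10 of 11 endothelial genes, 10 of 12 JAK-STAT3 pathway genes, 16 of 20 cell cycle genes, 10 of 13 matrix protease genes, 13 of 18 NF-kB targets, 7 of 9 osteoclast-like giant cell genes, 6 of 9 osteogenic genes and 7 of 11 T cell genes. Coverage was lower for mast cell genes (3 of 5), Wnt targets (5 of 11), adipocyte genes (4 of 9), neutrophil genes (3 of 7), keratinocyte and epithelium genes (4 of 10), red blood cell genes (2 of 6), Schwann cell genes (1 of 3), B and plasma cell genes (2 of 9) and skeletal muscle genes (1 of 14). The Schwann cell gene S100B was detected on 0 arrays and the B cell gene MS4A1 on 1.

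Matrix genes and the myofibroblast genes ACTA2 and TAGLN were high and even across samples. COL1A1 stood at 15.98 ± 0.06, FN1 (fibronectin) at 15.80 ± 0.12 and COL3A1 at 15.40 ± 0.22, and the smooth muscle actin gene ACTA2 at 15.91 ± 0.05 and TAGLN at 15.79 ± 0.07 (log2, SD, n = 7). The largest SDs in the fibroblast and matrix list were those of THY1 (13.43 ± 0.85) and FBN1 (13.76 ± 0.40). The median SD of the 24 members was 0.18, at percentile 0.26 of level-matched random lists, the one list at or below percentile 5, and 0 members had an SD above 1. Many of these probes lay near the top of the scale, where differences are compressed. Matching to the 100 genes nearest in level, chosen after the data were seen, gave percentile 2.81.

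The widest differences between samples lay in genes of skeletal muscle, keratinocytes and fat. All 8 kept skeletal muscle genes were highest in the averaged sample, where the median member stood 6.30 log2 units above the median of the 7 samples. ACTA1 (skeletal actin) was 16.04 there and 6.08 to 8.64 in the other 6 samples, and CKM (muscle creatine kinase) was 15.89 against 5.80 to 9.82. MYH2 (14.79), MYL2 (16.06) and CKMT2 (14.72) were also highest there. DES, a muscle filament gene of the contractile list, was 14.17 there and 5.75 to 10.12 elsewhere. The list's median SD of 2.84 exceeded all 10000 random lists (percentile 100). Without the averaged sample too few of its genes were kept for a score.

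Keratinocyte genes were high in tumours 4 and 9. KRT5, a basal keratinocyte keratin, was 15.40 and 15.35 in them and 5.87 to 9.11 in the other 5 samples. KRT14, its partner, was 15.91 and 15.85 against 7.95 to 9.71, and SFN was 14.89 and 14.52 against 5.87 to 7.99. Of 7 kept members, 5 had these tumours as their highest 2. The median member stood 2.97 log2 units above the median of the 7 samples in tumour 4 and 1.54 in tumour 9. The list's spread was at percentile 99.18. Leaving out tumour 4 lowered it to 83.38 and leaving out the averaged sample to 91.06. Among the 25 genes with the largest SD, RNASE7, KLK11, SPRR1A, KRT78, LGALS7, CST6, DSC3, PSORS1C2 and ANXA8L2 had the same highest 2 samples. The SD of KLK11 was 3.99 with its brightest probe and 2.12 with the mean of its probes. SFTA1P ran the other way, at 5.81 and 5.88 in tumours 4 and 9 and 12.40 to 13.89 elsewhere. EPCAM (9.65 ± 1.23, n = 7), a marker of simple epithelium, was 11.28 in tumour 4, 9.31 in tumour 9 and highest in tumour 2 at 11.32.

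Adipocyte genes varied as well, at percentile 99.06, a call kept when any single array or the averaged sample was left out. ADIPOQ, the fat cell hormone adiponectin, was 13.94 in tumour 5, 13.09 in tumour 8 and 6.27 to 10.09 elsewhere. PLIN1, a lipid droplet protein, was 11.25, 10.90 and 11.04 in tumours 5, 8 and 4 and at most 9.35 in the others. Of the 7 kept members, 3 had tumours 5 and 8 as their highest 2. LEP (leptin) differed less, at 10.66 ± 0.76 (n = 7).

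**Figure D2:**
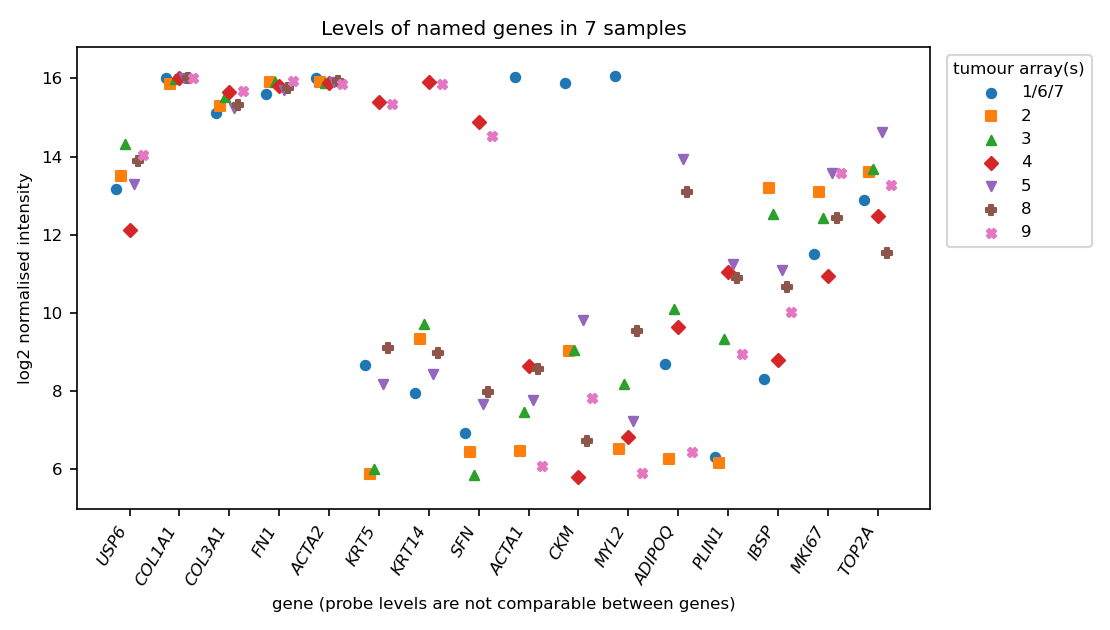
Log2 normalised intensity (vertical axis) of named genes (horizontal axis) with 1 point per sample, the first being the mean of arrays 1, 6 and 7. KRT5 and KRT14 are high in tumours 4 and 9, ACTA1, CKM and MYL2 are high in the averaged sample, and COL1A1 and ACTA2 vary little.

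Bone-related genes were highest in tumour 2. Of 7 kept osteogenic genes, 6 were highest there, with a median member 2.21 log2 units above the median sample. IBSP, a bone matrix protein, was 13.20 in tumour 2, 12.53 in tumour 3 and 8.32 to 11.09 elsewhere. ALPL (alkaline phosphatase) was 15.83 in tumour 2 against 13.27 to 14.99 elsewhere. RUNX2, a regulator of bone formation, was 13.86 ± 0.67 (n = 7), highest in tumour 9 at 14.64, with an SD of 0.52 over arrays 1, 6 and 7. The regulator SP7, detected on 4 arrays and outside the score, was 13.93 in tumour 2 and 6.24 to 11.33 elsewhere. The list's spread was at percentile 99.87, and at 87.29 without tumour 2. Osteoclast-like giant cell genes (percentile 99.63) were highest in tumour 2 for 6 of 9 members. SIGLEC15 was 14.08 there and close to that in tumour 9, at 13.77. DCSTAMP, which serves the fusion of such cells, was 12.08 in tumour 2, 11.70 in tumour 5 and at most 10.53 elsewhere. OSCAR was 13.25 in tumour 2 and 13.90 in tumour 5. CTSK (15.62 ± 0.38) and MMP9 (15.76 ± 0.37) varied less between samples.

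Matrix protease genes were also uneven, at percentile 99.60. The collagenase gene MMP1 ranged from 7.85 in tumour 4 and 8.24 in tumour 2 to 14.67 in tumour 9, and MMP3 from 5.92 in tumour 4 to 14.44 in tumour 9. MMP2 was lower in spread, at 13.75 ± 0.77 (n = 7), and was highest in tumour 4 at 14.90. MMP14 stood at 8.25 ± 0.87. Of the 13 members, 7 were lowest in tumour 4.

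Cell cycle genes were highest in tumour 5 for 11 of 20 members and lowest in tumour 4 for 7. MKI67 was 13.58 in tumour 5, 13.57 in tumour 9 and 10.95 in tumour 4. TOP2A was 14.63 in tumour 5, 12.47 in tumour 4 and lowest in tumour 8 at 11.54, and KIF20A was 13.63 in tumour 5 and 5.80 in tumour 4. CCNB1 differed less (12.68 ± 0.55, n = 7). The list lay at percentile 98.80, and at 93.92 without tumour 5. Interferon response genes were lowest in tumour 4, one of the keratinocyte-high tumours, for 15 of 17 members. IFIT1 was 11.93 in tumour 4 and 14.26 to 15.77 elsewhere, ISG15 was 11.31 against 14.16 to 15.61, and MX1, near the top of the scale, was 16.05 ± 0.02. Percentile 99.89 for this list became 38.76 without tumour 4, so the call rested on that sample.

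T cell genes (percentile 96.17) were highest in the averaged sample for 8 of 11 members and lowest in tumour 9 for 6. CD3D was 14.23 and 9.98 in these, CD8A 11.71 and 5.75 and LCK 12.40 and 6.59, while CD3E was 11.46 and 9.11. The lowest T cell scores were those of the keratinocyte-high tumours 9 (-1.38) and 4 (-1.11), and without both the percentile was 46.53. It was 80.45 without tumour 4, 65.24 without tumour 9, 94.44 without the averaged sample, 85.56 with BeadChip set as a block, 85.46 with genes detected on all 9 arrays and 94.69 with no detection filter. Contractile genes (95.15) and Wnt targets (95.12) passed by little. Leaving out any of 6 single arrays took contractile genes below the threshold, to 74.82 without tumour 2, as did leaving out the averaged sample (92.47), the mean of a gene's probes (79.39), genes detected on all 9 arrays (82.35), no detection filter (90.80) and BeadChip set as a block (94.89). Wnt targets stood at 91.55 without tumour 2, 89.47 without the averaged sample and 78.79 with no detection filter. CNN1 was 12.03 in tumour 2 and 13.81 to 14.77 elsewhere, SYNPO2 ran from 11.36 to 14.78, and the Wnt targets AXIN2 (11.75 ± 1.13) and LEF1 (12.97 ± 1.50, lowest in tumour 9 at 9.84) varied, and NKD1 ran from 8.38 to 11.28. LGR5 was 9.07 ± 1.26 (n = 7). In all, 11 of 25 scored lists reached percentile 95.

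The other 13 lists lay between the percentile limits, though 3 of them passed 95 under some settings. Mast cell genes did so with an offset of 50 (95.21), with the mean of a gene's probes (96.98), with BeadChip set as a block (95.88) and without tumour 3, 4, 5 or 9 (96.41 to 97.59). Neutrophil genes reached 96.77 on the deposited normalized values and immediate early genes 96.05 with genes detected on all 9 arrays. Inflammatory genes of the NF-kB list (percentile 81.18) were highest in tumour 9 for 9 of 17 members. In it IL6 was 14.21 and CXCL8, a neutrophil attractant, 14.71, against 6.09 and 6.05 in tumour 4, while the feedback inhibitors NFKBIA (15.38 ± 0.17) and TNFAIP3 (10.77 ± 0.35) varied little. Neutrophil genes (86.71) were highest in tumour 9 for 4 of 5 members. S100A8 was 12.91 there and at most 8.37 elsewhere, S100A9 14.78 and at most 13.44, and CXCR2 12.36 and at most 9.60. FCGR3B was 7.46 ± 0.85. Immediate early genes (84.50) were highest in tumour 9 for 8 of 13 members: FOS was 15.84 in tumour 5 and 15.74 in tumour 9, EGR1 15.04 and 15.28, JUN 15.75 and 14.32, NR4A1 12.83 and 15.16, ATF3 12.48 and 12.80. In the JAK-STAT3 list (82.02), STAT3 was 14.16 ± 0.26 and JAK1 13.87 ± 0.42, SOCS3 was 12.45 ± 1.04, LIF 11.50 ± 2.09 and IL6R 8.98 ± 1.50.

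TGF-beta and BMP response genes (percentile 77.88) were highest in tumour 9 for 8 of 11 members: INHBA was 14.22 there and 12.64 ± 1.08 over the samples, with SMAD7 at 12.79 ± 0.77, ID1 at 13.01 ± 0.52, ID2 at 13.51 ± 0.61 and TGFB1 at 11.20 ± 0.82. In the hypoxia and glycolysis list (78.52), LDHA was 15.53 ± 0.15, SLC2A1 13.38 ± 0.42, VEGFA 11.50 ± 0.97 and HK2 10.34 ± 1.26. Ribosomal protein genes (69.12) included RPL3 (14.85 ± 0.40), RPS3 (15.06 ± 0.51), RPL5 (14.98 ± 0.17), RPL8 (13.14 ± 0.56) and RPL10 (8.25 ± 1.27). Mitochondrial respiration genes (7.88) included NDUFA9 (13.21 ± 0.66), COX5B (14.42 ± 0.34), NDUFB8 (15.86 ± 0.22) and CYC1 (12.23 ± 1.31).

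Macrophage genes (percentile 60.19) were detected on all 9 arrays for 11 of 12 members and on 0 arrays for the other. CD68 was 14.35 ± 0.56, CD163 14.68 ± 0.22, CSF1R 15.31 ± 0.17 and C1QB 14.26 ± 0.66. MSR1 was 12.14 ± 1.08, with 10.45 in tumour 4 and 10.84 in tumour 9. Endothelial genes (79.39) included PECAM1 (13.91 ± 0.12), CDH5 (13.24 ± 0.52), VWF (16.03 ± 0.04), TEK (11.28 ± 1.11) and ROBO4 (9.90 ± 1.74). B and plasma cell genes (67.72) included CD79A (12.75 ± 0.64), POU2AF1 (9.82 ± 1.93), JCHAIN (9.41 ± 2.34) and MZB1 (8.03 ± 1.20). Mast cell genes (94.00) were highest in tumour 8 for 3 of 5 members and lowest in tumour 2 for 3; TPSAB1, mast cell tryptase, was 13.73 and 9.80 in these, CPA3 12.20 and 9.36 and TPSB2 9.25 and 6.23. Tumour 9 was low as well, with a score of -1.29 against -1.63 in tumour 2: CPA3 was 9.33 there, and KIT was 7.24 there and highest in tumour 5 at 12.79. The list of USP6 and its partners lay at 43.76. Red blood cell and Schwann cell lists had 4 and 2 kept genes and were not scored. HBA2 was 15.45 ± 0.21, HBB 13.46 ± 0.92, ALAS2 9.43 ± 1.73, AHSP 9.41 ± 1.14, MBP 12.85 ± 1.22 and SOX10 7.91 ± 2.16.

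**Figure D3:**
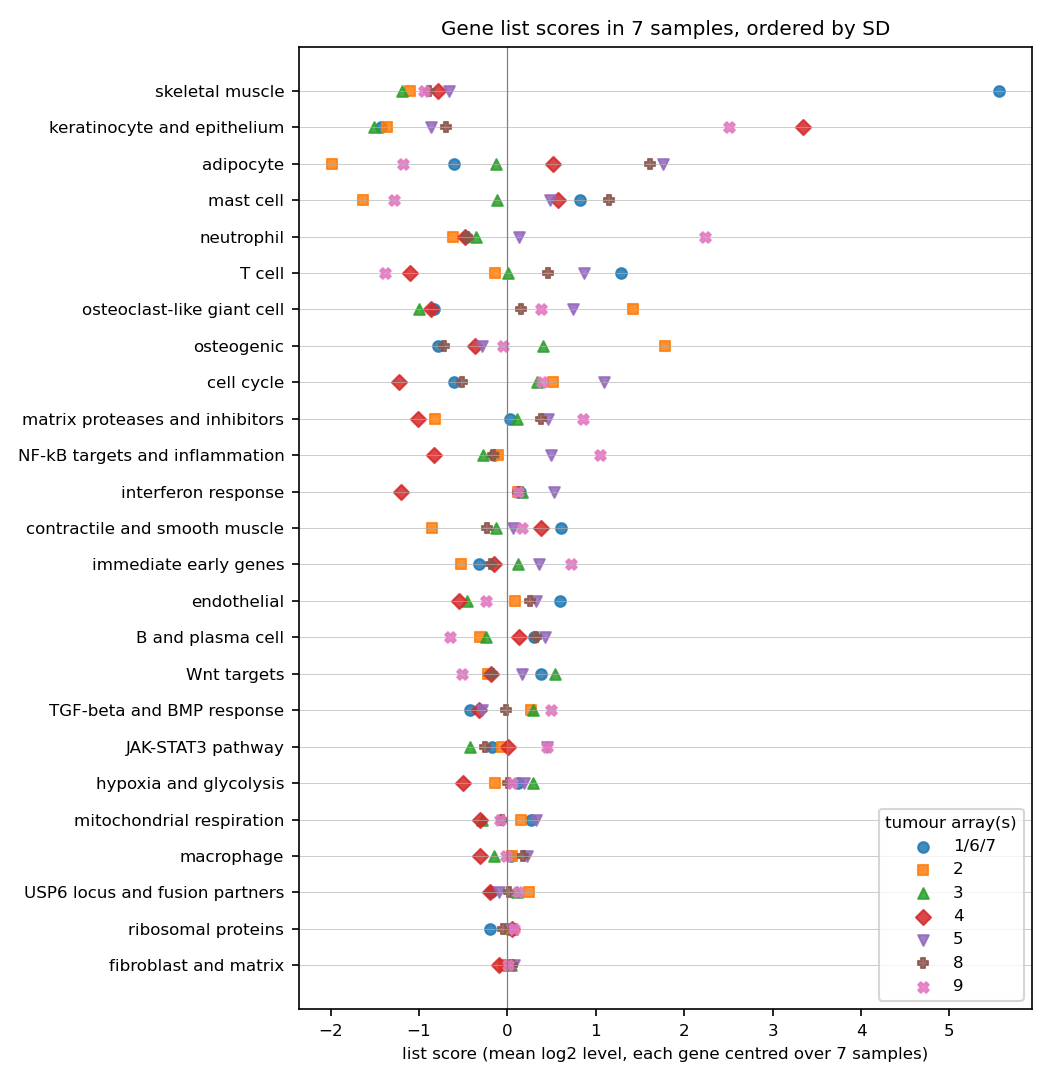
Scores of 25 gene lists (vertical axis) as mean centred log2 level (horizontal axis), 1 point per sample. Skeletal muscle stands at 5.56 in the averaged sample, keratinocyte and epithelium at 3.35 and 2.51 in tumours 4 and 9, and fibroblast and matrix between -0.09 and 0.07 in all 7 samples.

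Of the other genes with the largest SD, PLA2G4F was 13.64 in the averaged sample, 15.11 in tumour 4, 13.25 in tumour 9 and at most 8.34 elsewhere. THBS4, a matrix protein of tendon and muscle, ran from 6.04 in tumour 3 to 15.24 in the averaged sample, KCNJ8 from 5.97 to 14.11, SLC36A2 from 5.75 to 14.84, ECRG4 from 5.89 to 13.27 and CST1 from 5.79 to 13.40. ADH1B, an alcohol dehydrogenase, was 13.44 in tumour 8 and 13.12 in tumour 5 and 5.72 in tumour 9. IL24, a cytokine, was 14.72 in tumour 9, 14.56 in tumour 3 and 5.88 in tumour 2. Its SD was 3.31 with its brightest probe and 1.64 with the mean of its probes.

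Whether programmes varied together was examined next, over 300 pairs of list scores. Immediate early and neutrophil genes, both high in tumour 9, had the smallest p: Pearson's r was 0.86 (exact permutation p = 0.000794, adjusted p = 0.238, n = 7) and Spearman's rho 0.893 (exact permutation p = 0.0123, adjusted p = 0.736). Leaving out the 2 samples farthest from the median immediate early score gave r = 0.938, and with both scores adjusted for BeadChip set r was 0.877. No r was taken within a set, since each holds fewer than 6 distinct samples. B and plasma cell and mast cell genes followed, at r = 0.877 (exact permutation p = 0.0103, adjusted p = 0.455) and rho = 0.75 (exact permutation p = 0.0663, adjusted p = 0.736), with r = 0.776 without the 2 farthest samples. TGF-beta and BMP response against B and plasma cell genes gave r = -0.895 (exact permutation p = 0.0105, adjusted p = 0.455) and rho = -0.679 (exact permutation p = 0.110, adjusted p = 0.758), and r = -0.824 without the 2 farthest. In all, 0 of 300 pairs passed after adjustment and 27 had an unadjusted exact p under 0.05. The smallest possible exact permutation p of 0.000198 would become 0.0595 when adjusted over 300 pairs, so no single pair could pass alone. With all 9 arrays as separate tumours, 1 pair passed, at r = 0.863 for immediate early and neutrophil genes.

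USP6 is the driver gene of this tumour, and genes and lists were set against its level. The largest correlations were those of hypoxia and glycolysis genes at r = 0.779 (exact permutation p = 0.0498, adjusted p = 0.430, n = 7), interferon response genes at r = 0.736 (exact permutation p = 0.103, adjusted p = 0.430) and TGF-beta and BMP response genes at r = 0.732 (exact permutation p = 0.0468, adjusted p = 0.430). Spearman's rho was 0.464 for hypoxia (exact permutation p = 0.302), 0.214 for interferon (exact permutation p = 0.662) and 0.893 for TGF-beta (exact permutation p = 0.0123, adjusted p = 0.308). Without the 2 samples farthest from the median USP6 level, r was -0.360 for hypoxia and -0.479 for interferon, so these relations rested on those samples, and 0.810 for TGF-beta. Adjusting for BeadChip set gave 0.780, 0.724 and 0.726 for hypoxia, interferon and TGF-beta. Fusion partner genes without USP6 gave r = 0.469 (exact permutation p = 0.291) and rho = 0.714 (exact permutation p = 0.0881). In all, 0 of 25 lists passed.

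Gene by gene, 0 of 14233 genes passed on USP6 with limma (smallest adjusted p = 0.155), and 871 had an unadjusted p under 0.05. None of the 6 leading genes passed. CYP2D6, a drug-metabolising enzyme, had a slope of 2.36 ± 0.25 (SE) log2 units per unit of USP6, TAFA5 3.25 ± 0.38 and LOC440570 2.49 ± 0.29. SFTPD, a surfactant protein, had a slope of -2.98 ± 0.31, NEBL -2.69 ± 0.32 and DCST1 -2.23 ± 0.29. Adjusted over the list alone, 1 of 11 TGF-beta and BMP genes passed with limma, INHBA (an activin subunit) at 1.35 ± 0.28 (adjusted p = 0.0210, or 0.400 over all genes). Of 20 cell cycle genes 1 passed, PCNA (a replication clamp) at 1.78 ± 0.38 (adjusted p = 0.0430, or 0.419 over all genes); PCNA was chosen after its value was seen. Every other list had 0 genes adjusted over the list alone. Array weights in limma gave 5903 genes, but the weights were 7.73 for tumour 3, 4.10 for the averaged sample and at most 1.04 elsewhere. Tumour 3 and the averaged sample thus weighed most in that fit, and whether the count depends on them was not tested. All 9 arrays as separate tumours gave 20 genes.

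A technical comparison set the 4 arrays on 3 other BeadChips against the 5 on the first. Matrix protease genes had the smallest p, with scores 0.60 higher on the 4 arrays (0.34 against -0.26, exact permutation p = 0.183, adjusted p = 0.906). Skeletal muscle scores differed by 1.95 (exact permutation p = 0.341, adjusted p = 0.906), with 1 of the 3 alike arrays in one set and 2 in the other. In all, 0 of 25 lists and, with limma, 0 of 14234 genes passed (smallest adjusted p = 0.950), 262 genes had an unadjusted p under 0.05, and 0 genes passed in any list adjusted over the list alone. The smallest exact permutation p possible for a list, 0.00794, would become 0.198 when adjusted over 25 lists, so no single list could pass alone. This comparison counts arrays 1, 6 and 7 separately, so its n exceeds the number of distinct samples. Without them, 4 arrays against 2 gave 0 of 12915 genes with limma (287 at an unadjusted p under 0.05) and 0 of 21 lists (smallest exact permutation p = 0.133, where 15 regroupings allow 0.0667 at the lowest), and with them as a random block limma gave 461 genes.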

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

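The tests of the alike arrays, of the keratinocyte genes and of the skeletal muscle genes were chosen after the results were seen; the counts of splits and orders were planned. Of 51 values tested over 7 samples (25 list scores and 26 genes), 6 had an end sample whose gap to its neighbour, as a share of the whole range, exceeded Dixon's 95% limit for 7 samples, where chance gives about 1 in 20. The 25 genes with the largest SD were picked for their spread. Tumour 4 stood low in the interferon response score (0.764) and tumour 9 high in the neutrophil score (0.739). The averaged sample stood high in the skeletal muscle score (0.922) and in MYL2 (0.642), ACTA1 (0.744) and CKM (0.602). ACTA1 and CKM belong to that list, so these flags are not independent. The 6 of 51 therefore cannot be set against a rate of 1 in 20.

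Arrays 1, 6 and 7 differed from each other far less than other arrays did. A shared BeadChip is excluded, since they lay on 3 BeadChips. A candidate explanation is 1 RNA run on 3 arrays, with separate pieces of 1 tumour or separate similar tumours as others. On the 500 genes most variable among the other 6 arrays, their median SD was 0.236, which is 0.391 of the smallest of any other set of 3 arrays. The limit set first was under 0.25, with any larger ratio as the outcome against 1 RNA, so by that rule the test went against it. Many of those sets hold 2 of the 3 arrays, which makes the rule a poor measure. Against sets with at most 1 of them, a comparator added after that value was seen, the ratio was 0.247. A comparator chosen in this way cannot overturn the rule, so whether 1 RNA was run on 3 arrays stays open. No known repeat was used here to set the size of technical noise, and no biological explanation was tested.

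Skeletal muscle genes stood far above the other samples in the averaged sample. A fault of 1 array is excluded, since the SD of the score over the 3 arrays was 0.0544. Adjacent skeletal muscle in the block is a candidate explanation: of a second list of 16 muscle genes, 11 were kept, all 11 were highest in this sample, and the median member was 5.43 above the median of the 7 samples, where 2 was required. A first form of this test, against the mean of the other samples, gave 5.88. The sample was picked for its high muscle genes, and the filter of 5 arrays counted it as 3 arrays. Passing the limit with more muscle genes was therefore likely in advance and does not separate adjacent muscle from another source. Abundant muscle transcripts were near the top of the scale (ACTA1 16.04, CKM 15.89), and the contractile list also holds muscle genes such as DES. Beyond the second list, no biological explanation was tested.

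Keratinocyte genes stood high in tumours 4 and 9. A BeadChip effect is excluded, since the tumours lay on 2 BeadChips. Squamous epithelium in the block is a candidate explanation: of a second list of 16 keratinocyte genes, 7 were kept, 5 had these tumours as their highest 2, and the median member stood 2.76 above the median of the 7 samples in tumour 4 (members 0.12 to 7.38) and 2.633 in tumour 9 (members -0.55 to 4.45), where 2 was required in each. A first form, which averaged both tumours, gave 3.43 and was replaced because it grouped samples by the value tested. In the first keratinocyte list the median member stood 1.54 above in tumour 9, below that limit. Both tumours were picked for their high keratinocyte genes, so more such genes do not separate squamous epithelium from another source. KRT5 and KRT14 reached 15.35 to 15.91 in these tumours. Apart from the second list, no biological explanation was tested.

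In the comparison of BeadChip sets, 100 of 100 splits of the 9 arrays gave at least as many genes as the real 0. With a real count of 0 this holds for any data and says nothing about chance. The highest other split gave 3713 genes. Of the 12 splits with any gene, 12 were among the 19 that kept arrays 1, 6 and 7 together, so large counts point to the structure of the samples. For USP6, the 100 of 100 orders of the levels that gave at least the real 0 are as empty a result, 3 gave any gene, and the highest other gave 574.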

How the results depend on the processing

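Alternatives that treat arrays 1, 6 and 7 separately, leave them out together, block on them, use the 100 genes nearest in level or leave out tumours 4 and 9 were chosen after the data were seen. The count of 11 lists with a wide spread was 7 with genes detected on all 9 arrays, where skeletal muscle, keratinocyte and adipocyte lists had too few genes for a score, and ran from 6 to 12 when a sample was left out. It was lowest without the averaged sample, where skeletal muscle was not scored and contractile, Wnt, T cell and keratinocyte lists stood at 89.47 to 94.44. It was 8 to 12 under the other settings. Genes associated with USP6 numbered 0 except for 5903 with array weights, which ran from 0.102 for tumour 4 to 7.73 for tumour 3 over 7 samples, and 20 with all 9 arrays as separate tumours; the cause was not tested. Pairs of lists numbered 0 except for 1 with all 9 arrays. Genes differing between BeadChip sets numbered 0 except for 461 with arrays 1, 6 and 7 as a random block (consensus correlation 0.966), where the contrast rests mainly on array 1 against arrays 6 and 7; 2893 then had an unadjusted p under 0.05. No list passed on USP6 or between BeadChip sets under any setting run, and leave-one-out counts of genes and pairs were 0; for pairs and for lists between BeadChip sets this says nothing about stability, since 1 item alone could not pass (smallest adjusted p 0.0595 over 7 samples and 0.417 over 6 for pairs, 0.198 for BeadChip lists). Genes detected on all arrays numbered 9944 where every probe of the gene had to be detected and 12376 at a detection p below 0.05, against 11733. No alternative processing reversed the sign of the leading correlations, USP6 slopes and BeadChip differences that were recomputed, but leaving out the 2 samples farthest from the median turned the sign of r for some lists on USP6, among them hypoxia (-0.360), interferon (-0.479) and keratinocyte genes (0.765), and for some pairs, such as interferon and macrophage genes (0.815 to -0.827). Other USP6 probes and detection from the deposited value table were not run, since the array has 1 named USP6 probe and that table holds no detection p. Signal over background limits genes near the floor of 5.59.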

Other observations

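The test of adipocyte genes was chosen after the values were seen. Adipose tissue in the block may account for the high adipocyte genes of tumours 5 and 8. Of a second list of 12 adipocyte genes, 10 were kept and 1 had these tumours as its highest 2. The median member stood 0 above the median of the 7 samples in tumour 5 and 0.52 in tumour 8, where 1 was required in each. The value in tumour 5 also lay under the lower limit set as the outcome against fat, so by that rule the test went against this explanation. The score of the second list, a mean over the same genes, was nevertheless highest in tumours 8 (1.104) and 5 (0.937), followed by tumour 4 (0.796). Median member and mean score thus gave different readings, so whether fat accounts for the pattern stays open. Members ran from -1.33 to 4.40 in tumour 5 and from 0 to 5.44 in tumour 8. Single members were thus far above the median sample, and some fat in these blocks is not excluded. A first form of the test gave 1.39 and is not used, because it averaged samples picked by the value tested.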
